A study of Caenorhabditis elegans with 4 samples.

How the data were processed

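Chromatin immunoprecipitation followed by sequencing was carried out on embryos of the Caenorhabditis elegans strain OP228, in which the nuclear hormone receptor NHR-237 carries a GFP and 3xFlag tag on a transgene introduced by biolistic bombardment. Per the labels' protocols, animals were grown at 20 °C, crosslinked with formaldehyde and sonicated, and chromatin was precipitated with anti-GFP antibodies, while a part of each lysate was kept as input DNA. The series holds 4 samples, 2 ChIP samples and 2 input samples, each ChIP sample sharing its replicate number with an input sample. The labels do not say whether replicates 1 and 2 came from separate cultures, so the spread between them may be technical only.

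The data used here are 3 deposited lists of binding regions, one for each ChIP sample and one combined list that belongs to no single sample. Per the file headers, coordinates are on WormBase WS220, and the source field of each line names SPP followed by the irreproducible discovery rate (IDR) procedure. The aligner, the tool versions, the thresholds, the use of the input samples in calling and the way the replicates were combined are not given in the sources used here. Each deposited region has a start, an end, a score and a peak number. The scale of the deposited score is not named in the file headers. It ran from 0.0044 to 2.79 in the replicate 1 list, from 0.0032 to 3.24 in the replicate 2 list and from 1.51 to 3.35 in the combined list, with 306, 863 and 1123 regions tied at the highest value. The deposited peak numbers ran from 1 to the length of each list without repeats. They decreased with rising score (Spearman's rho across regions of -1.00, -1.00 and -0.84), so a smaller number was read as a better rank. The peak number has the most distinct values (1679 in the combined list, against 557 distinct scores), and it was used as the order of regions except in 2 alternatives, which used the score for the agreement of the replicate lists and for the share of X. The score and the peak number are the authors' values and were used to order regions within a list. One count of the regions with a score of 1 or more in each replicate list was made as an alternative, and it assumes that the scores of these lists share a scale, which is not stated. The lists hold no read counts, so the depth of each sample is unknown, and intervals below are exact Clopper-Pearson 95% binomial intervals over regions that cover counting error only.

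Regions of the nuclear chromosomes were compared with bedtools 2.31.1 and with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 under Python 3.11.15; figures were drawn with matplotlib 3.10.9. Regions were taken as shared when they overlapped by at least 1 bp. The overlap of the replicate lists was set against 1000 random placements of the replicate 2 regions within their chromosome (one-sided permutation test, smallest possible p = 0.001). Where several regions of the other list overlapped, the one with the smallest peak number was paired. Rank agreement was tested with 100000 permutations. The number of combined regions per chromosome was set against the length from the first to the last base covered by any of the 3 lists, with a two-sided exact binomial test per chromosome, Benjamini-Hochberg adjustment over the 6 chromosomes, and 100000 multinomial draws for the whole distribution. These tests treat regions as independent, and regions are not replicates.

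The following choices were made before the data were examined: the comparisons, the alternative settings, and the rule for the regions named. The rule names the first 25 combined regions that overlap a region of both replicate lists. It also names the 3 best regions of each replicate list that overlap no region of the other. For their order the plan gave the authors' score, in its most variable column, with ties by position. Reading the peak number as that column was decided with the lists in hand, from counts of distinct values. Ordered by the score alone, 1123 tied combined regions would have been placed by position. The alternatives were an overlap of at least 50% of both regions, midpoints within 200 bp, the best 1000 regions or the better 50% of each list, and the best 1679 regions of a single replicate list in place of the combined list. Planned analyses of gene starts, annotated features, 30 gene lists, sequence words and the nhr-237 locus were not run. The gene table at hand is on the WBcel235 assembly, which is not the build of the regions, and no genome sequence was used here. For gene starts the plan also allowed another build if its largest offset was far below the window of 1000 bp. That offset was not assessed here. Regions are therefore named by position alone.

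The overlap and chromosome counts were tested on simulated data. For the overlap comparison, lists of 8318 and 12682 random regions with 2000 regions placed in both gave an estimate of 1990 shared regions. In shorter unrelated lists, with fewer placements drawn over all chromosomes, 7 of 100 comparisons had a permutation p of 0.05 or less. Simulated regions were placed uniformly, so this rate does not measure the error of the test on the real lists. For the chromosome comparison, 1679 simulated regions with a doubled density on X gave an observed over expected number of 1.69, where 1.70 was built in.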

Results

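Binding of NHR-237, a member of the nuclear hormone receptor family of transcription factors, was profiled in C. elegans embryos through a GFP tag. The series addresses where in the genome the tagged factor is bound in a mixed population of males and hermaphrodites. It comprises 2 ChIP samples, each with its own list of regions, 2 matched input samples, and 1 combined list. The replicate 1 list held 8326 regions, of which 8318 lay on the nuclear chromosomes and covered 3.69 Mb. The replicate 2 list held 12698 regions, of which 12682 were nuclear and covered 5.65 Mb. The combined list held 1679 regions, all nuclear, covering 0.757 Mb. Most regions had one fixed width, which was 464 bp in replicate 1 (98.9% of regions), 470 bp in replicate 2 (99.0%) and 490 bp in the combined list (87.8%). No read counts accompany these lists, so differences in list length could not be set against depth. The replicate 2 list was 1.53 times as long as the replicate 1 list.

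The first comparison asked how far the replicate samples found the same regions. The best-ranked regions almost all overlapped a region of any rank in the other sample, and the low-ranked ones mostly did not. Of the best 1000 regions of replicate 1, 72.0% overlapped one of the best 1000 of replicate 2. Rank here is the deposited peak number, and whether it follows signal strength is not stated. Of the 8318 nuclear regions of replicate 1, 4917 overlapped a replicate 2 region, which is 59.1% (95% interval 58.0 to 60.2). Random placement of the replicate 2 regions gave 939 ± 29.6 overlaps (SD, n = 1000 placements), and the highest of these was 1044. The observed number was 5.24 times the random mean (one-sided permutation p = 0.001, the smallest that the placements can give). Seen from the longer list, 5173 of the 12682 replicate 2 regions, or 40.8% (39.9 to 41.7), overlapped a replicate 1 region.

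Recurrence depended on rank. In the best decile of replicate 1, with peak numbers 1 to 834, 830 of 832 regions overlapped replicate 2, or 99.8% (99.1 to 100.0). The share was 79.4% (76.5 to 82.1) in the third decile and 53.3% (49.9 to 56.7) in the fifth. It was 32.3% (29.1 to 35.5) in the last decile, where random placement gave 11.3% and at most 14.6%. In replicate 2 the share was 96.8% (95.7 to 97.7) in the best decile and 19.6% (17.5 to 21.9) in the last. Across the 4917 overlapping pairs, the peak numbers of the replicates correlated with a Spearman's rho of 0.63 and a Pearson's r of 0.51 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give). This correlation is across regions, which are not independent replicates. Positions were closest for regions with small peak numbers: the median distance between paired midpoints was 11 bp for the first 100 replicate 1 regions, 26 bp for those numbered 101 to 1000, and 72 bp for the rest.

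**Figure D1:**
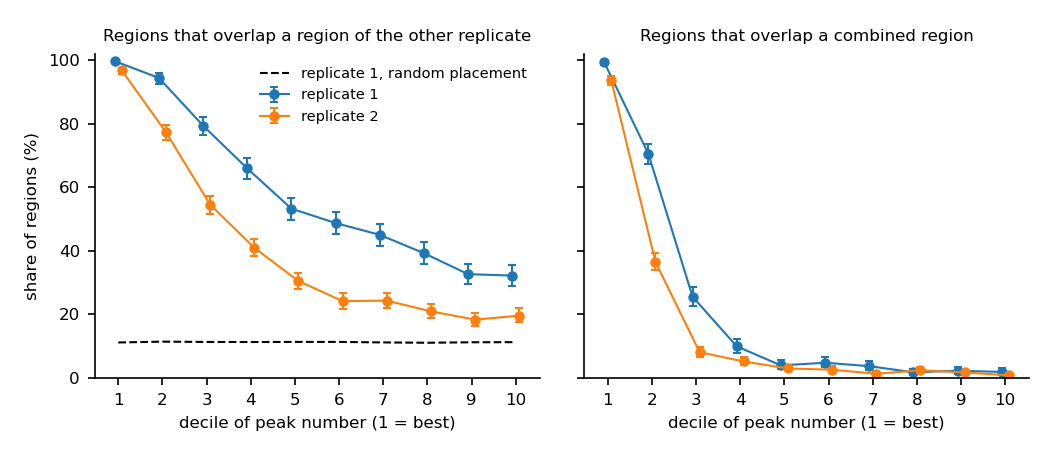
Share of the nuclear regions of each replicate list (y axis, %) that overlap a region of the other replicate list (left) or a combined region (right), by decile of the peak number within the list (x axis, 1 is the best). Points are shares, bars are 95% binomial intervals and the dashed line is the mean of 1000 random placements for replicate 1; the share in the other list falls from 99.8% to 32.3% for replicate 1 and from 96.8% to 19.6% for replicate 2.

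**Figure D2:**
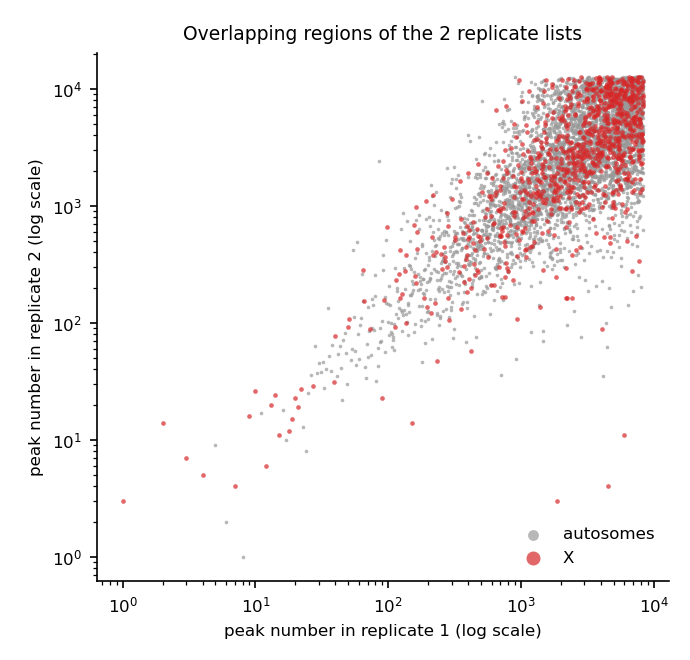
Peak numbers in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) of the 4917 overlapping pairs of nuclear regions, with pairs on X in red and pairs on the autosomes in grey. One replicate 2 region can pair with several replicate 1 regions. The pairs rise together with a Spearman's rho of 0.63. X stands out only at the smallest peak numbers, in the lower left corner. It held 16 of the first 25 nuclear regions of replicate 1 and 14.7% of those ranked 26 to 100.

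Few regions with small peak numbers were found in one replicate list alone. Among replicate 1 regions without a counterpart, the best was on chromosome V at 10965411 to 10965874, with peak number 82. It was followed by chromosome I 5164799 to 5165262 with peak number 371 and chromosome II 9054525 to 9054988 with peak number 886. Among replicate 2 regions without a counterpart, the best were on mitochondrial DNA at 1122 to 1591 and 5219 to 5688, with peak numbers 50 and 463. The next was on chromosome IV at 3368644 to 3369113, with peak number 466. Of these 6, the regions on V and IV overlapped a combined region.

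The combined list was then compared with the lists it stands beside. As a combined list whose source field names the IDR procedure, it is not independent of the replicate lists. A high share of counterparts, above all for the best ranks, is therefore in part built in. Nearly every combined region had a counterpart in each sample: 1669 of 1679 overlapped replicate 1, or 99.4% (98.9 to 99.7), and 1674 overlapped replicate 2, or 99.7% (99.3 to 99.9). Both samples held a counterpart for 1664 combined regions, a single sample did for 15, and no combined region lacked both. None of the combined regions had exactly the coordinates of a region in either replicate list. Most regions have a fixed width that differs between the lists, so few exact matches were possible. Of the best decile of replicate 1, 99.4% (98.6 to 99.8) overlapped a combined region, against 70.6% (67.3 to 73.6) of the second decile and 25.6% (22.7 to 28.7) of the third. For replicate 2 these shares were 93.7% (92.2 to 95), 36.5% (33.9 to 39.2) and 8.12% (6.68 to 9.77). The median combined region had its counterpart at peak number 816 in replicate 1 and 829 in replicate 2. The best combined region with a counterpart in replicate 1 alone was number 117, on chromosome V at 10965556 to 10965736. The best with a counterpart in replicate 2 alone was number 1197, on chromosome IV at 3368638 to 3369127. With an overlap of at least 50% of both regions, the share found fell to 92.8% for replicate 1 and 94.6% for replicate 2.

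The first 25 combined regions were nearly the same in both samples. Counted among nuclear regions, all 25 had their counterpart among the first 25 of replicate 1, and 24 of them among the first 25 of replicate 2, where the remaining one ranked 26. Their paired midpoints in the replicates lay a median of 7.5 bp and at most 61 bp apart. They were 278 to 628 bp wide, with a median of 368 bp. Of these 25 regions, 16 lay on X, 4 on III, 2 on II, 2 on IV, 1 on V and none on I. The X chromosome held 64% (42.5 to 82.0) of the first 25 regions and 15.7% of the other 1654 (260 regions; two-sided Fisher's exact test, p = 9.6e-08, a comparison chosen after the values were seen). The share of X was 64% in the first 25 nuclear regions of replicate 1 and 60% in those of replicate 2. Among combined regions numbered 26 to 100 it was 13.3% (6.58 to 23.2). Counted over the first 50 regions it was 36% (Fisher's exact test against the rest, p = 0.00064), and over the first 100 it was 26% (p = 0.012).

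The 16 X regions were spread along the chromosome. In order of rank they lay at 6296268 to 6296756 (first in the combined list, first in replicate 1 and peak number 3 in replicate 2), 13700576 to 13701010, 11093859 to 11094358, 806513 to 806860, 2996844 to 2997396, 14525491 to 14526069, 8036057 to 8036661 and 11937313 to 11937657. The remaining X regions lay at 9465593 to 9466005, 4209011 to 4209462, 5429355 to 5429699, 1626945 to 1627317, 12362878 to 12363314, 16681897 to 16682182, 11605601 to 11606228 and 16056265 to 16056757. The median distance between neighbours on X was 1.21 Mb and the shortest was 332 kb. On the autosomes, the second region of the list lay on II at 10563358 to 10563686 and ranked first in replicate 2, and the third lay on III at 3867400 to 3867742. Chromosome IV held regions at 4749889 to 4750245 and 654754 to 655121. Chromosome III also held 8043759 to 8044068, 10758962 to 10759314 and 7854490 to 7854767. The last were 8561249 to 8561537 on II and 9344125 to 9344455 on V. All 25 had the highest score of 3.35, which 1123 of the 1679 combined regions share, so that both their order and their place among the first 25 rest on the peak number alone. X held 16.8% (14.7 to 19.1) of the 1123 tied regions and 15.6% of the other 556 (two-sided Fisher's exact test, p = 0.58, an alternative chosen after the values were seen). That comparison cannot decide whether X stands out among the first 25, since they are a small part of the tied regions and the score does not order them. Which genes lie at these positions was not analysed here.

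**Figure D3:**
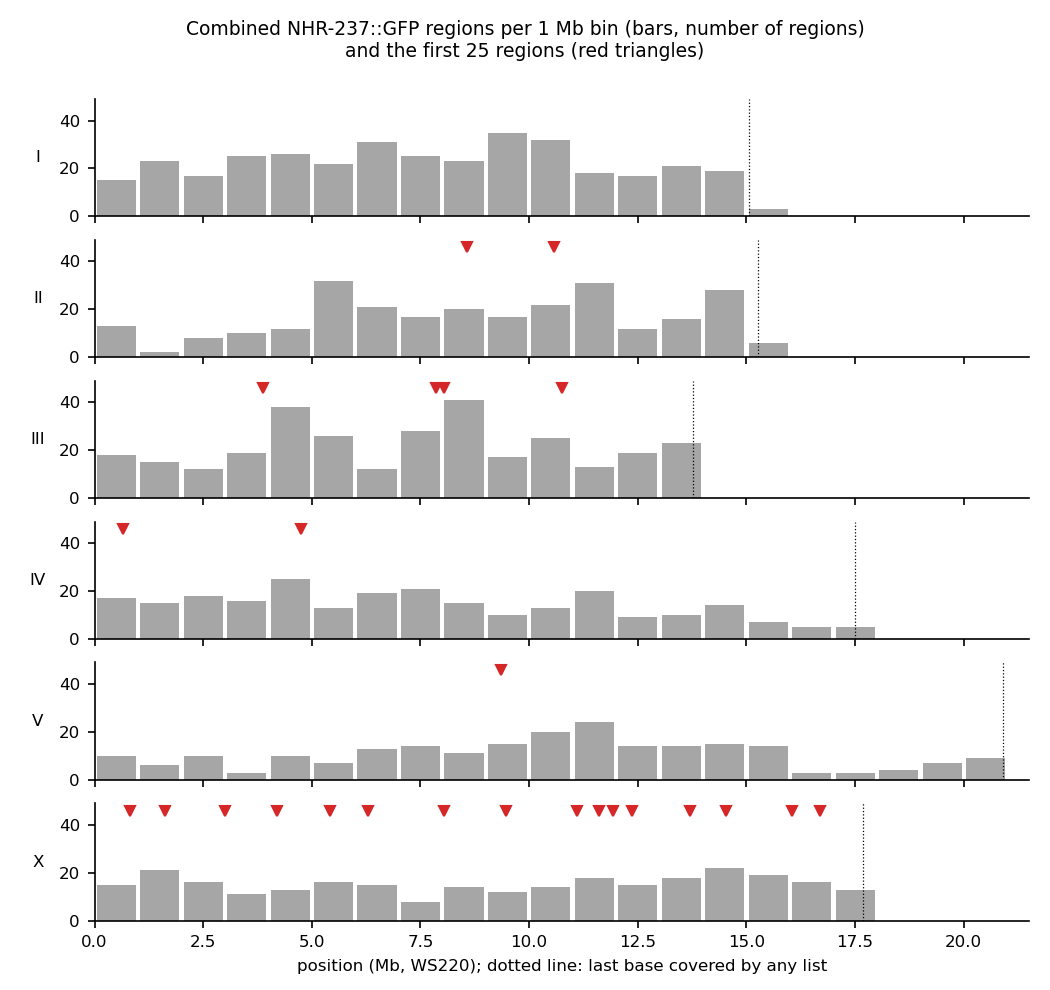
Number of combined regions per 1 Mb bin (grey bars, y axis) along each nuclear chromosome (x axis, Mb on WS220), with the first 25 combined regions as red triangles. The last bin of each chromosome is partial. X carries 16 of the 25 triangles, from 806513 to 16682182, while its tallest bar is lower than the tallest bar of each autosome.

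The next comparison asked how the combined regions were divided among chromosomes. Chromosomes I and III held more regions than their length accounts for, and chromosomes IV and V fewer. Chromosome I held 352 regions, or 23.4 per Mb, which was 1.39 times the expected number (95% interval 1.27 to 1.53; adjusted p = 2.3e-10, exact binomial test). Chromosome III held 306, or 22.2 per Mb, at 1.32 times (1.19 to 1.47; adjusted p = 6.3e-07, exact binomial test). Chromosome V held 226, or 10.8 per Mb, at 0.64 times (0.57 to 0.73; adjusted p = 2.8e-14, exact binomial test). Chromosome IV held 252, at 0.86 times (0.77 to 0.96; adjusted p = 0.014, exact binomial test). Chromosome II with 267 regions (1.04 times, 0.93 to 1.16; adjusted p = 0.46, exact binomial test) and X with 276 (0.93 times, 0.83 to 1.04; adjusted p = 0.24, exact binomial test) did not pass the test. None of 100000 multinomial draws departed as far from the expected counts (permutation p = 1e-05, the smallest the draws can give). The call for chromosome IV ended among the better 50% of combined regions (adjusted p = 0.15, exact binomial test) and when regions within 5 kb were merged (adjusted p = 0.14, exact binomial test).

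**Figure D4:**
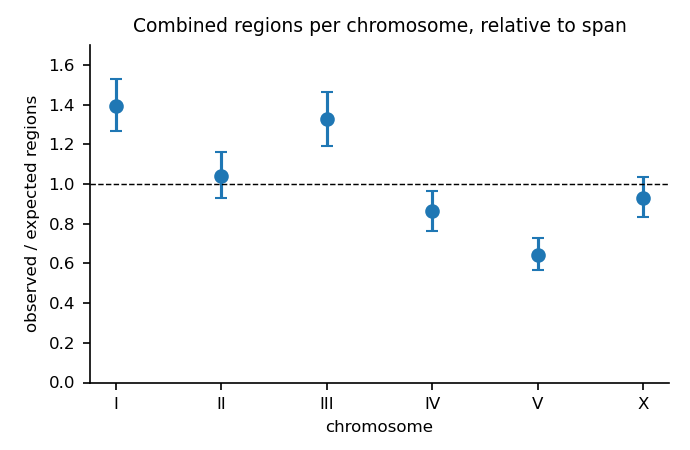
Observed over expected number of combined regions (y axis) for each nuclear chromosome (x axis), where the expected number follows from the length covered by the lists. Points are ratios, bars are 95% binomial intervals and the dashed line marks 1; I and III lie above it at 1.39 and 1.32, and IV and V below it at 0.86 and 0.64.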

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

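Both replicate lists hold regions on mitochondrial DNA, which the comparisons between nuclear regions left out and the combined list does not contain. They were noticed after the data were seen. The replicate 1 list has 8 such regions, which cover 24.2% of the 13839 bp between the first base and the last listed mitochondrial base; the best, at 12107 to 12570, has peak number 367. The replicate 2 list has 16, which cover 42.7%; the best, at 13016 to 13243, has peak number 21, and 10 of the 16 share the highest score of that list. Of the 8 regions of replicate 1, 6 overlap a replicate 2 region, where random placement on mitochondrial DNA gives 5.84 on average (one-sided permutation test with 1000 placements, p = 0.631). Among the first 1679 regions of each list, 4 in replicate 1 and 13 in replicate 2 are mitochondrial, against 0 of the 1679 combined regions.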

How the results depend on the processing

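The alternatives that merged nearby or overlapping regions or scored overlap differently for the deciles were chosen after seeing the data. So were the shifted background, the cutoff at a score of 1, and every alternative for the first 25 regions, the chromosome middles and the spacing. The plan named the authors' score, in its most variable column, for rank agreement and for the order of regions. Reading the peak number as that column, with the score as the alternative, was decided with the lists in hand. The test of an X-wide excess was run in 3 forms: the count past the first 25 regions spoke against such an excess, the count over all regions held against a ratio of 1 left it open, and the form kept holds that count against the interval of the first 25. A test that merged regions within 5 kb was dropped for the X regions among the first 25, since they lie too far apart for it to join any. The concentration of X was seen by peak number, and the score cannot test it, since 1123 combined regions tie at the highest score. X held 16.8% of these tied regions, with no call against the rest (Fisher's exact test, p = 0.58). With the score in place of the peak number, the replicate lists correlated with a Spearman's rho of 0.63 and a Pearson's r of 0.69, against 0.63 and 0.51. Of 59 comparisons with an alternative setting, 49 kept their direction and their side of the threshold or stayed within the error of the main value. An overlap of at least 50% of both regions moved the share of combined regions found to 92.8% in replicate 1 and 94.6% in replicate 2, and the share of the best decile that overlaps a combined region to 87.5% in replicate 1 and 87.5% in replicate 2. With the better 50% of the replicate 1 list, 97.8% of the combined regions were found. The deficit on chromosome IV missed the threshold among the better 50% of combined regions (0.88 times the expected number) and after merging regions within 5 kb (0.90 times); both use fewer regions. Merging overlapping entries lowered the share of combined regions with a neighbour within 1000 bp from 7.10% to 2.38% and ended that call (permutation p = 0.177). For chromosome II, which passed no test, the ratio turned from 1.04 to 0.98 without replicate 2 and was 1.06 without replicate 1; the cause was not tested. The replicate 2 list was 1.53 times as long as that of replicate 1, and 1.25 times among regions with a score of 1 or more, if the scores share a scale. The overlap of the replicate lists ranged from 51.6% (midpoints within 200 bp) to 72.0% (best 1000 regions of each list), each with a permutation p of 0.001. No paired analysis was possible because no region list of the input samples, which share replicate numbers with the ChIP samples, was analysed here. The alternative settings for gene starts, annotated features, gene lists and sequence words were not run, for want of an annotation and a genome of the same build. With no read counts, the depth behind a region and the depth of each library set a limit that was not measured here.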

Other observations

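All tests in this part were chosen after the data were seen, and only for the pooled test on chromosome V was the prediction written before the value was computed. Autosomal combined regions were denser in the middle of 3 equal parts of each chromosome than the equal share of 33.3%: 574 of 1403 lay there, or 40.9% (38.3 to 43.5; exact binomial test, p = 3.0e-09, adjusted over 7 tests 2.1e-08). The share was highest on V, with 111 of 226 regions or 49.1% (42.4 to 55.8; exact binomial test, adjusted p = 4.5e-06). It was 39.5% on I, 40.4% on II and 39.5% on III, with adjusted p-values of 0.028, 0.028 and 0.035 in exact binomial tests. The shares of 37.7% on IV (exact binomial test, adjusted p = 0.142) and 29.0% on X (23.7 to 34.7; exact binomial test, adjusted p = 0.142) did not pass the threshold. The calls for the autosomes together and for V held among the better 50% of regions, without replicate 1, without replicate 2 and after merging regions within 5 kb, and those for single other chromosomes did not all hold. Among the better 50%, II had 34.6% (exact binomial test, adjusted p = 0.85), and I and III had 41.2% and 41.4% (adjusted p = 0.068 for both, exact binomial test). III had 36.9% without replicate 2 (exact binomial test, adjusted p = 0.22) and 38.8% after merging (adjusted p = 0.098, exact binomial test), while IV passed at 40.2% without replicate 2 (exact binomial test, adjusted p = 0.035). Autosomal regions that overlapped no combined region had a middle share of 36.6% (35.3 to 38) in replicate 1 and 36.2% (35.2 to 37.2) in replicate 2.

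After identical entries were removed, 7.10% of 1676 regions had another midpoint within 1000 bp, against 3.50% for placements on the same chromosome and 3.79% for placements within the same 1 Mb bin (permutation p = 0.001 for both, the smallest that 1000 placements can give). At this distance the excess sat in overlapping entries: once these were merged, in the list and in the placements alike, 39 of 1636 regions had such a neighbour against a random mean of 31.5 (permutation p = 0.177). Within 2000 bp an excess remained after the same merging, with 155 regions against 89.2 (permutation p = 0.001). The densest 50 kb window held 8 regions, on chromosome I from 9064508 to 9113486; placements within 1 Mb bins gave a window at least as dense with a permutation p of 0.239.

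The concentration of X regions among the first 25 combined regions was weighed against technical explanations. It was seen by peak number, and the tied score cannot test it. One library alone does not account for the concentration, since X makes up 60% of the first 25 regions in the replicate with the lower share (Fisher's exact test, p = 5.7e-06 in replicate 2 and 7.2e-07 in replicate 1). Neither do repeated entries at one locus, since the closest X regions among the 25 lie 332 kb apart, nor a gain of one X segment, since the 16 regions fall in 13 separate 1 Mb bins. An excess of that size along all of X does not account for it, since X has 0.93 times the expected number over all combined regions (95% interval 0.83 to 1.04) against 3.63 times among the first 25 (2.41 to 4.65), but a smaller X-wide excess is not excluded, and this rule was set with both intervals known. Past the first 25, X held 18.5% of replicate 1 regions, 18.6% of replicate 2 regions and 15.7% of combined regions, against 17.7% expected from length. No test of the replicate shares against length is given here. Also open is signal that any anti-GFP precipitation from embryos could give at these sites. No ChIP from animals without the tag was analysed here. Binding of a complex specific to X, such as that of dosage compensation, is a candidate explanation. It was not tested, because positions of its sites were not used here. The design gave no biological explanation to test.

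The low number of regions on chromosome V was tested against the hypothesis that its outer parts alone are sparse, and the answer depends on the reference. In the middle of 3 equal parts, V had 15.9 regions per Mb and the other autosomes together 22.6, a ratio of 0.71 (95% interval 0.57 to 0.87; exact binomial test, p = 0.00077). That pooled value rests on I, II and III, with 27.7, 21.2 and 26.4 regions per Mb in their middle parts. The middle of IV had 16.3, so that V stood at 0.97 times IV (0.73 to 1.30; exact binomial test, p = 0.89). The density over all chromosomes, outer parts included, was 16.8 per Mb. By the rule written before the value was computed, a pooled interval below 1 speaks against the hypothesis, and this interval lay below 1. The comparison with IV was not part of that rule, and IV itself held 0.86 times its expected number of regions. The hypothesis therefore failed its rule against the pooled autosomes and stays open against IV alone. In the outer parts V had 0.47 times the density of the other autosomes together (0.39 to 0.58).

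One region with a small peak number stands apart between the samples: the combined region number 117 on chromosome V, 181 bp wide, corresponds to peak number 82 in replicate 1 and overlaps nothing in the 12698 regions of replicate 2.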
